A study of Mus musculus with 2 samples.

How the data were processed

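Small RNA of whole heart from male mice of the F1 hybrid strain B6CASTF1/J at 2 months of age was sequenced as 2 libraries, which the sample descriptions number as different males. Both carry the same donor identifier in the labels, so that they come from separate animals rests on those descriptions and on the biological replicate numbers. Per the labels, total RNA was used and the library was limited to short fragments of the size of mature microRNAs. The labels give 1 tissue and no treatment, so the libraries form 1 group of 2 biological replicates.

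The values used were raw read counts per microRNA gene, deposited by the authors as 1 file per library with no header. Per the deposited text that accompanies each file, reads were placed on the mouse assembly mm10 with the GENCODE M21 annotation. The aligner, its version and its settings were not given in the sources used here. Each file holds 4 rows that name no gene, for reads that were unmapped, mapped to several places, in no gene or in more than 1 gene, and 2202 microRNA genes. It has 3 count columns, which count a read without regard to strand, on the strand of the gene, and on the opposite strand. The sum of each column, with the rows that name no gene, was the same within a library, so a read mapped to several places was counted in its own row and in no gene row. A count is for the whole hairpin gene, and both arms of a hairpin add to it. These rules lower the counts of genes whose mature sequence lies at more than 1 place in the genome.

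The column of reads on the strand of the gene was used as the main measurement. Rows that name no gene were left out of library sizes and tests. CPM values (counts scaled to a library total of 1000000) were computed from the deposited counts over the sum of all microRNA gene counts of a library, and are not the authors' values. The 2202 identifiers all matched the annotation release named in the accompanying text, from which gene symbols, positions on mm10, host genes and hairpin sequences were taken. Host genes were other genes that span the hairpin on the same strand. A hairpin was called exonic when it overlapped any exon of any annotated transcript of its host, and intronic otherwise. Stretches of sequence shared between microRNA genes were searched among the hairpins on either strand, since a genome sequence was not used here. The longest stretch shared with a microRNA gene at another place was recorded per gene.

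The tests, the 20 gene lists with 166 genes, the alternatives and the rule for named genes were fixed before the data were examined. Of the 166 list genes, 7 were matched through an older symbol. The genes named are the 20 with the highest mean CPM, all members of the cardiac and striated muscle, skeletal muscle enriched, endothelial, smooth muscle, erythroid and liver lists, the 3 most abundant members of each other list, both genes of 6 related pairs, and, among genes past the low-count filter that differ beyond counting noise at a mean of at least 10 CPM, the 5 with the largest ratio between the libraries in each direction. A few further genes are named beside them and are said to be chosen after their values were seen. A gene was called detected at 2 CPM or more in both libraries. Shares of counts are given with exact Clopper-Pearson 95% intervals per library. The reads carry no molecular identifiers that were used here, so these intervals and the floor of 3 counts (0.822 CPM in replicate 1 and 0.787 CPM in replicate 2) cover counting error only. The median log2(CPM + 1) of each list was set against 10000 random lists of the same size drawn from all 2202 genes, as a description of these libraries. Related genes were compared as log2 ratios of CPM + 0.5 within each library. With 2 libraries, the smallest two-sided p of an exact sign-flip permutation test is 0.5, so no such ratio was tested.

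The spread between the replicates was estimated with edgeR 4.0.16 in R 4.3.3, with an intercept only, TMM normalization and the genes past filterByExpr, and its interval came from 100 bootstrap draws of the genes. Differences between the 2 libraries were tested per gene with an exact two-sided binomial test of the counts against the ratio of the TMM library sizes, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test compares 2 libraries with counting noise and says nothing of conditions. Neighbouring genes were adjacent microRNA genes on the same strand at most 10 kb apart, and their levels were compared with 10000 shuffles of the levels over the genes. Genes with a copy number in the symbol were compared with the other genes by 10000 shuffles. The alternatives were the other strand columns, other detection limits, all uniquely mapped reads as the denominator, the most abundant gene left out, a pseudocount of 1, DESeq2 1.42.0 size factors or plain library totals, other low-count filters, other distances, a copy defined by a shared stretch of 20 bases, and each replicate left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

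Both statistics across genes were tested on simulated data with the real means and library sizes. The estimated coefficient of variation was 0.0994, 0.291 and 0.456 where 0.1, 0.3 and 0.5 had been simulated on 2202 genes. Counts of the simulated replicate comparison were drawn with counting noise only, which is what the test assumes. These simulations therefore check the calculation and give no rate of false calls under the wider spread of the real libraries. With no changed gene, 0 of 336 tested genes were called in this simulated comparison. With 200 genes changed, as many up as down, the test called 25 of 25 genes raised by a factor of 4. It called 20 of 25 raised by 2 and 44 of 50 raised by 1.5. Of genes lowered to 0.25, 0.5 and 0.667 of their level, it called 21 of 22, 18 of 22 and 35 of 47. Of unchanged genes it called 2 of 140. With 3 genes raised for each gene lowered, the estimated ratio of the library sizes was off by 9.92%, and 37 of 135 unchanged genes were called. Small ratios of abundant genes therefore rest on the scaling.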

Results

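MicroRNA genes were profiled by small RNA sequencing of whole heart from 2 male mice at 2 months of age. The animals were B6CASTF1/J, an F1 hybrid of the laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ. Replicate 1 held 10362589 reads and replicate 2 held 10483233 reads. Reads on the strand of a microRNA gene numbered 3650782 in replicate 1 and 3810675 in replicate 2, which was 35.8% ± 0.792 of the reads (SD, n = 2). Reads mapped to several places made up 47.2% ± 1.07, unmapped reads 12.2% ± 0.951, and uniquely mapped reads outside microRNA genes 4.79% ± 0.673 (SD, n = 2 each). Because reads mapped to several places enter no gene, the levels below are those of reads with a single place in the genome. All values are means over the 2 libraries unless a replicate is named.

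A profile of 1 tissue describes which microRNA genes have counts and what share of the counts each holds. The counts were not corrected for how well each mature sequence is recovered in library preparation. Ranks and ratios between different genes are therefore those of counts and may differ from those of the microRNAs in the tissue. The most abundant gene by these counts was Mir378a, at 132638 CPM ± 21763 (SD, n = 2) and 13.3% ± 2.18 of the counts. It lies in an intron of Ppargc1b, the gene of a coactivator of mitochondrial metabolism, on chromosome 18 from 61397835 to 61397900 of mm10. The let-7 genes Mirlet7i, Mirlet7b and Mirlet7g followed at 83854 CPM ± 18283, 69280 CPM ± 1200 and 69037 CPM ± 539, and Mirlet7d was at 41777 CPM ± 18205 (SD, n = 2 each). Mir23a, on chromosome 8 from 84208518 to 84208592 with no host gene on its strand, was at 62771 CPM ± 2635, and its paralog Mir23b on chromosome 13 was at 54223 CPM ± 5299. Mir126a, which overlaps an exon of an annotated transcript of the endothelial gene Egfl7, was at 61220 CPM ± 12739. It lies on chromosome 2 from 26591357 to 26591429. Mir143, known from smooth muscle, was at 49706 CPM ± 884, and Mir139 was at 39880 CPM ± 1714. These 10 genes held 66.4% ± 1.19 of the microRNA counts (SD, n = 2). Their share was 67.3% in replicate 1 (Clopper-Pearson 95% interval 67.2 to 67.3) and 65.6% in replicate 2 (65.5 to 65.6).

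Mir22, which overlaps an exon of an annotated transcript of Tlcd2, was at 29551 CPM ± 22296 (SD, n = 2), the widest spread among the 20 most abundant genes. Mir26b, in an intron of the phosphatase gene Ctdsp1, was at 28348 CPM ± 10514, Mir99a at 26642 CPM ± 1617 and Mir149, in an intron of the glypican gene Gpc1, at 19956 CPM ± 13491. The remaining genes of the 20 were Mir29a, Mir191, Mir125a, Mir30a, Mir30d and Mir30e, with means between 9878 and 12872 CPM. Together the 20 genes held 83.6% ± 1.16 of the counts (SD, n = 2). Of the 2202 genes, 337 reached 2 CPM in both libraries, 128 reached 100 CPM and 15 reached 10000 CPM. No read was counted for 1480 genes in either library. For reads with a single place in the genome, this allows a level of up to 0.822 CPM in replicate 1 and 0.787 CPM in replicate 2. Reads mapped to several places are not covered by this bound, and 1087 of the 2202 genes share at least 20 bases with another microRNA gene.

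**Figure D1:**
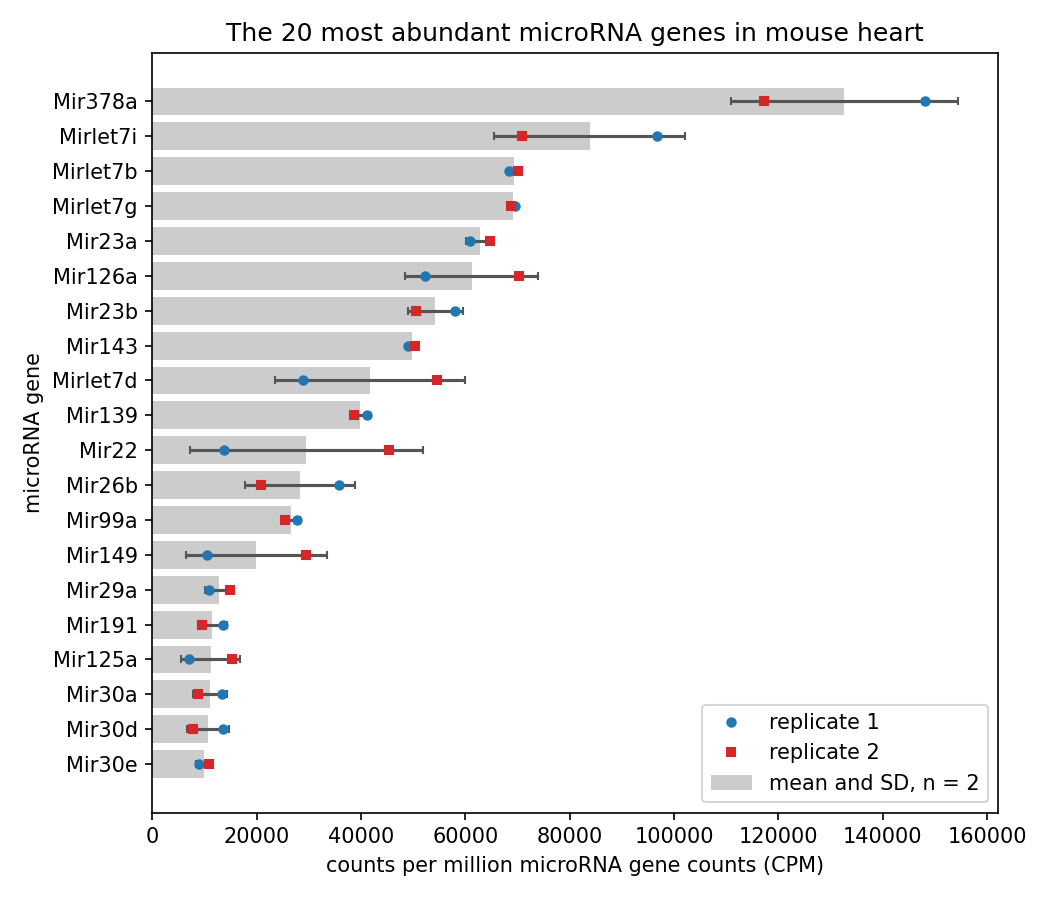
Levels of the 20 most abundant microRNA genes, in CPM. Grey bars are the means and lines the SD of 2 libraries, and points are the replicates. Mir378a stands highest at 132638 CPM, and Mir22 and Mir149 differ most between the replicates in relation to their means.

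Among microRNA genes linked to heart muscle, Mir208a and Mir499, in introns of myosin heavy chain genes, were at similar mean levels. Their order differed between the libraries, with Mir208a at 1329 and 4265 CPM and Mir499 at 2601 and 2507 CPM in replicates 1 and 2. Mir208a, in an intron of the cardiac myosin gene Myh6 on chromosome 14 from 54949060 to 54949142, was at 2797 CPM ± 2077. Mir499, in an intron of Myh7b on chromosome 2 from 155622880 to 155622958, was at 2554 CPM ± 66.2, and Mir208b, in an intron of Myh7 on chromosome 14 from 54975700 to 54975776, was at 71.1 CPM ± 65.7 (SD, n = 2 each). The genes for miR-1 and miR-133a, which are known as abundant microRNAs of heart muscle, had few counts. Of these, Mir1a-2 had 251 counts in replicate 1 and 150 in replicate 2, and Mir1a-1 had 6 and 20. Mir133a-1 had 19 and 21 counts, and Mir133a-2 had 8 and 8. Each of these 4 genes shares a stretch of at least 28 bases with another microRNA gene, and reads that lie within such a stretch are counted for no gene, so their levels are uncertain. The whole cardiac and striated muscle list held 0.549% ± 0.206 of the counts (SD, n = 2), with 6 of 7 members detected. These 4 genes are among the 7, and reads within their shared stretches are missing from this share. It may therefore be too low, and it cannot rank heart muscle microRNAs against those of other cell types. The median level of the list lay at percentile 99.9 of random lists, which were drawn from genes of which most had no count.

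Lists of other cell types of the heart were led by the endothelial and smooth muscle genes. The endothelial list held 6.12% ± 1.27 of the counts (SD, n = 2), nearly all of them from Mir126a, while Mir126b on the opposite strand had 0 counts in replicate 1 and 4 in replicate 2. The endothelial share depends on strand, because Mir126a and Mir126b overlap and the column without strand counts such reads for neither. The smooth muscle list held 5.39% ± 0.0938, with Mir143 above and Mir145a at 4242 CPM ± 1822. The fibroblast and matrix linked list held 1.83% ± 0.227, with Mir29a at 12872 CPM ± 2762, Mir21a at 3206 CPM ± 1836 and Mir214 at 1394 CPM ± 1237. Of its 9 members 7 were detected, and 6 share at least 22 bases with another microRNA gene. The leukocyte list held 0.965% ± 0.139, with Mir150 at 3745 CPM ± 459, Mir155 at 3304 CPM ± 266 and Mir146 at 1570 CPM ± 131. The erythroid list held 0.314% ± 0.0203, with Mir451a at 1571 CPM ± 501, Mir486 at 1076 CPM ± 270, Mir144 at 444 CPM ± 46.2 and Mir3107 at 45.0 CPM ± 18.0 (SD, n = 2 each). Without strand the erythroid share was 0.0576%, since Mir451a and Mir486 overlap genes on the opposite strand and had 0 counts there. The medians of these lists lay between percentiles 99.26 and 100 of random lists.

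Lists of genes known from tissues other than heart held small shares of the counts. Reads within stretches shared between genes are missing from these shares, so for members with such stretches a small count does not show a low level. The epithelial list held 0.0347% ± 0.00462 of the counts (SD, n = 2), led by Mir200c at 163 CPM ± 15.6 and Mir203 at 146 CPM ± 39.3, with Mir200b at 11.4 CPM ± 2.50. The neuronal list held 0.0300% ± 0.00123, led by Mir128-1 at 223 CPM ± 19.0, Mir137 at 43.3 CPM ± 9.65 and Mir128-2 at 19.2 CPM ± 2.29. No read was counted for 4 of its 9 members, and 8 members share at least 22 bases with another gene. The skeletal muscle enriched list held 0.0176% ± 0.0187, with Mir206 at 170 CPM ± 188 and Mir133b at 5.64 CPM ± 0.550. Its share was 0.00430% in replicate 1 and 0.0308% in replicate 2, and Mir133b shares 21 bases with Mir133a-1. The liver microRNA gene Mir122 was at 120 CPM ± 31.1. The endocrine list held 0.00450% ± 9.9e-05, with Mir7-1 at 19.5 CPM ± 2.44, Mir7b at 14.1 CPM ± 0.616 and Mir375 at 8.60 CPM ± 1.40. Of the 4 endocrine members, 2 share at least 22 bases with another microRNA gene. The sensory list held 0.00156% ± 0.000578, with Mir183 at 9.09 CPM ± 1.62, Mir182 at 6.10 CPM ± 3.98 and Mir96 at 0.399 CPM ± 0.177 (SD, n = 2 each). None of the 14 genes of the X-linked testis cluster reached 2 CPM in both libraries. Of these, 10 had no count in either library, and the most counted were Mir741 with 7 and 2 counts, Mir470 with 3 and 4, and Mir871 with 1 and 1. The median of the X-linked testis list was 0, as was that of 86.09% of random lists of its size, so its rank says nothing. The epithelial, neuronal, skeletal muscle, liver, endocrine and sensory lists lay between percentiles 92.61 and 99.57 of random lists, since most of the 2202 genes had no count.

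**Figure D2:**
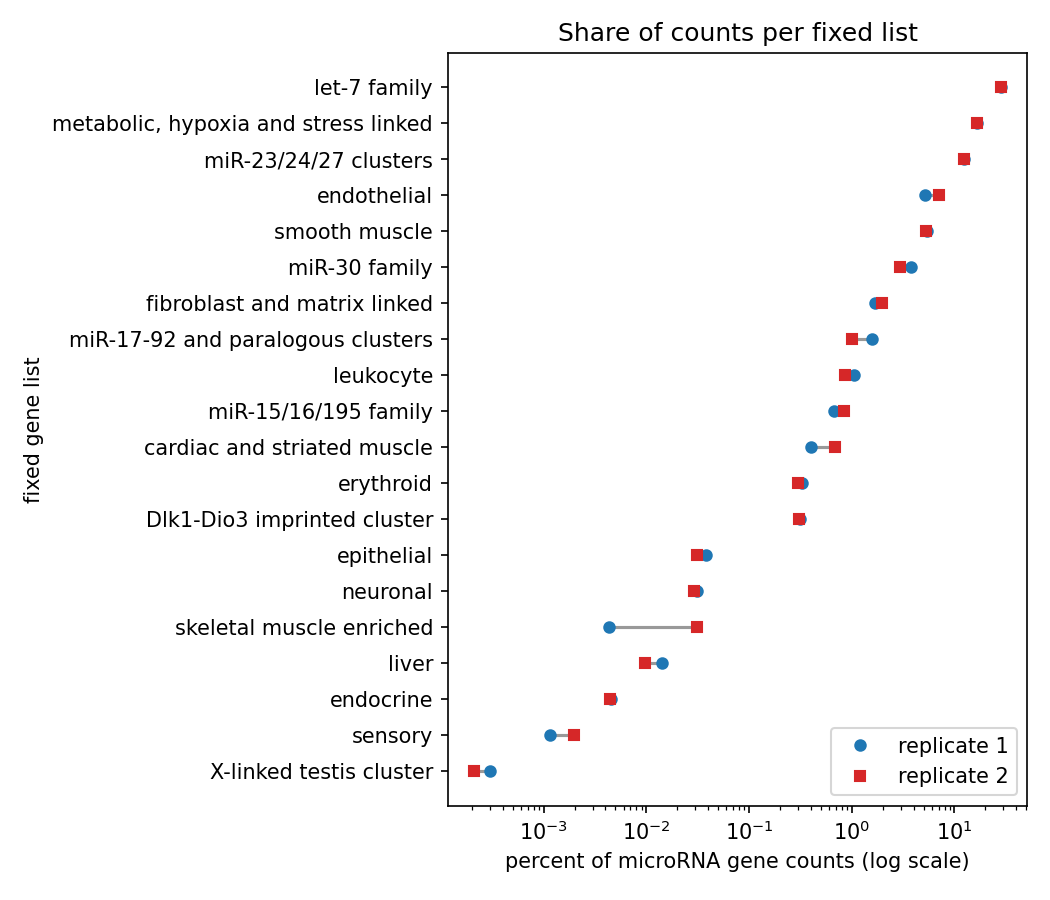
Share of microRNA gene counts held by each of the 20 fixed gene lists, in percent on a log scale, with 1 point per replicate. The let-7 family holds 28.4% on average and the X-linked testis cluster 0.000256%, and the skeletal muscle enriched list shows the widest gap between the replicates. Reads within stretches shared between genes enter no gene and are missing from these shares. Stretches of at least 22 bases are shared by 4 of 7 members of the cardiac and striated muscle list.

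Among microRNA families, the let-7 family held the highest share of counted reads, 28.4% ± 0.0416 (SD, n = 2), with 12 of 12 members detected. Of these members, 6 share at least 22 bases with another microRNA gene, as do 2 of 6 in the miR-30 family. Each other family or cluster given here also has such members, among them Mir16-1 and Mir16-2. Reads within these stretches enter no gene. The shares may therefore be too low, and the order of families and their leading members is that of counted reads only. The list of metabolic, hypoxia and stress linked genes held 16.5% ± 0.144, most of it from Mir378a and Mir22, with Mir34a at 2620 CPM ± 853. Its share was 4.18% without strand, where Mir378a has 0 counts because Gm25301 overlaps it on the opposite strand, and 3.70% with Mir378a left out. The paralogous clusters of miR-23, miR-24 and miR-27 held 12.5% ± 0.0375. In these, Mir27b was at 5721 CPM ± 1198, far below Mir23b of the same cluster at 54223 CPM. The miR-30 family held 3.39% ± 0.578, led by Mir30a at 11105 CPM ± 3252, Mir30d at 10650 CPM ± 4087 and Mir30e at 9878 CPM ± 1421. The miR-17-92 cluster and its paralogs held 1.30% ± 0.414, with Mir93 at 6052 CPM ± 3107, Mir92-1 at 2225 CPM ± 97.9 and Mir17 at 1887 CPM ± 831. The miR-15, miR-16 and miR-195 family held 0.753% ± 0.114, with Mir15b at 2804 CPM ± 772, Mir15a at 1490 CPM ± 875 and Mir195a at 1352 CPM ± 324. The imprinted Dlk1-Dio3 cluster on chromosome 12 held 0.311% ± 0.00152 (SD, n = 2), with 38 of 45 members detected. Its leading members were Mir127 at 1049 CPM ± 50.2, Mir411 at 362 CPM ± 64.5 and Mir541 at 306 CPM ± 45.9. The medians of these family lists lay at percentiles 99.99 to 100 of random lists, which were drawn from genes of which most had no count.

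Ratios of related genes within a library were compared for 6 pairs, and with 2 libraries no exact permutation test of them can give a p below 0.5. Mir208a exceeded Mir208b in both libraries, by 52.8 times in replicate 1 and 36.1 times in replicate 2, a mean log2 ratio of 5.45 ± 0.39 (SD, n = 2). Mir208a made up 98.2% of the counts of this pair in replicate 1 (Clopper-Pearson 95% interval 97.8 to 98.5) and 97.3% in replicate 2 (97.1 to 97.6). Mir143 exceeded Mir145a, its neighbour 1301 bases away, with a mean log2 ratio of 3.62 ± 0.67. Mir451a exceeded Mir144, its neighbour 99 bases away, by 4.67 times in replicate 1 and 2.55 times in replicate 2, and this order turned in the column without strand, where Mir451a has no count because a gene on the opposite strand overlaps it. The order of Mir208a and Mir499 differed between the libraries, with a log2 ratio of -0.97 in replicate 1 and 0.77 in replicate 2. The sum of Mir1a-1 and Mir1a-2 against Mir206 gave 0.92 in replicate 1 and -2.75 in replicate 2. In the column without strand it gave -4.21 and -5.75, since Mir1b overlaps Mir1a-2 on the opposite strand and Mir1a-2 has no count there. Both Mir1a genes share 28 bases with another microRNA gene, and Mir206 shares no stretch of 15 bases or more. Reads within the shared stretch enter no gene, so this ratio cannot rank miR-1 against miR-206. The sum of Mir133a-1 and Mir133a-2 against Mir133b gave 0.39 ± 0.16 (SD, n = 2), with under 30 counts per gene sum in each library. The Clopper-Pearson 95% intervals of the Mir133a share, 40.2 to 69.3% and 44.2 to 73.0%, leave the order open. These genes share at least 21 bases with another microRNA gene, and reads within such a stretch enter no gene. More depth would not remove this limit.

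The libraries followed each other across genes and still differed by far more than counting noise. Over the 337 detected genes, log2(CPM + 1) in the 2 libraries had a Pearson r of 0.976 and a Spearman rho of 0.962 across genes, which are not independent replicates. The biological coefficient of variation was 0.370 over 320 genes in edgeR (95% interval 0.332 to 0.412 from a bootstrap over genes). That interval covers the choice of genes and not the choice of animals. With a single library per animal, the coefficient also holds differences in library preparation. The coefficient was 0.333 in the lowest, 0.420 in the middle and 0.344 in the highest of 3 groups of genes by level. A chi-square test of the counts of these genes gave 280421 on 319 degrees of freedom, so the files hold separate libraries. By the exact binomial test, 206 of 320 genes differed between the libraries at an adjusted p under 0.05, with 98 higher in replicate 2 and 108 higher in replicate 1. The split was 93 and 112 with DESeq2 size factors. It turned to 118 and 95 without the low-count filter, 89 and 87 at 10 CPM or more in both libraries, and 91 and 90 without strand. The filter and strand settings also change the TMM library sizes and the genes tested, so the split follows the scaling too. Of the 206 genes, 33 were more than 2 times higher in replicate 2 and 27 more than 2 times higher in replicate 1. The test compares these 2 animals and their libraries, and not conditions.

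The skeletal muscle microRNA gene Mir206, on chromosome 1 from 20679010 to 20679082, showed the largest ratio in favour of replicate 2 among genes past the low-count filter at a mean of at least 10 CPM. It had 135 counts in replicate 1 and 1154 in replicate 2, a log2 ratio of 3.02 (exact binomial test, Benjamini-Hochberg adjusted p = 7.35e-190). Mir133b, 3686 bases from it on the same strand, had 22 and 20 counts. Mir101a followed with a log2 ratio of 2.25, Mir208b with 2.23, Mir215 with 2.20 and Mir214, which overlaps an exon of Dnm3os, with 2.11. Among genes past the low-count filter, the largest ratio in favour of replicate 1 was that of Mir26a-1, which had 261 counts against 11, a log2 ratio of -4.58 (exact binomial test, Benjamini-Hochberg adjusted p = 2.79e-65), and it shares 25 bases with another microRNA gene. Gm49347, Mir674, Mir669e in the Sfmbt2 intron and Snord43, a gene with the symbol of a small nucleolar RNA, followed at -2.30, -2.25, -2.09 and -1.74.

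The 5 leukocyte genes that passed the low-count filter were lower in replicate 2 by the exact binomial test over all genes, under TMM, DESeq2 and plain scaling alike, and 5 were also lower when adjusted over the list alone. In replicate 2 the summed level of the leukocyte list was 0.808 times that of replicate 1, a log2 ratio of -0.308. The median absolute log2 ratio over all 320 compared genes was 0.436, and 206 of them passed this test, so such a shift is common between these libraries. Of the miR-17-92 list, 8 of 10 tested genes were lower and 1 higher in replicate 2, both over all genes and adjusted over the list alone, and the count of lower genes was 6 of 13 without the low-count filter. Of the cardiac and striated muscle list, Mir208a and Mir208b were higher in replicate 2, by log2 ratios of 1.67 and 2.23. Mir499 and Mir1a-2 were lower, by -0.07 and -0.82. The sign of Mir499 turned without the low-count filter, through the change in TMM library sizes alone. The let-7 list had 9 of 12 genes lower and 2 higher, and 6 lower and 3 higher without the filter, where the TMM library sizes also change. Over the remaining lists the members went both ways or were few. For example, the Dlk1-Dio3 list had 10 genes higher, 8 lower and 17 that did not pass among 35 tested, and 9 higher and 8 lower when adjusted over the list alone.

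**Figure D3:**
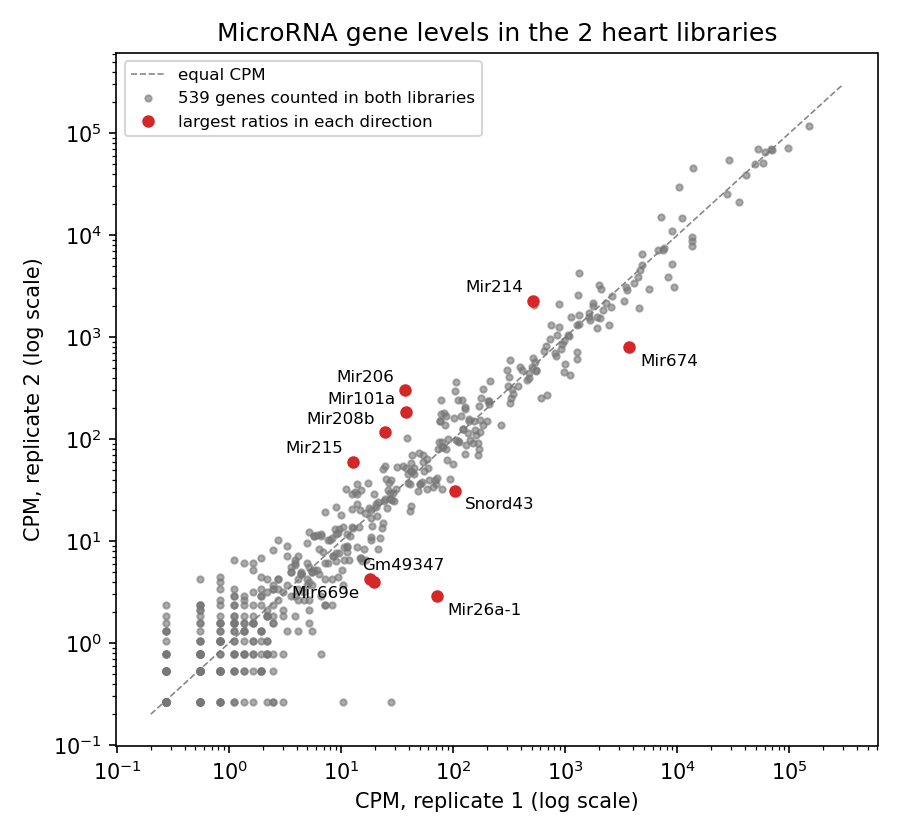
Level of each of 539 microRNA genes with a count in both libraries, in CPM on log scales, with replicate 1 across and replicate 2 upwards. The dashed line marks equal levels, and the named red points are the 5 largest ratios in each direction among genes past the low-count filter at a mean of at least 10 CPM, from Mir26a-1 at a log2 ratio of -4.58 to Mir206 at 3.02.

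Neighbouring microRNA genes, which are often processed from a shared primary transcript, were closer in level than shuffled genes. Over 355 adjacent pairs on the same strand at most 10 kb apart, the mean difference of log2(CPM + 1) was 1.54, against 1.92 ± 0.20 (SD of 10000 shuffles), with a one-sided permutation p of 0.0248. Among detected genes alone the mean difference was 2.56 over 99 pairs, against 4.01 in shuffles. At a distance limit of 2 kb the permutation p was 0.1518, so the call ended there.

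Genes that carry a copy number in their symbol were compared with the others, because identical copies lose reads in this kind of counting. The 119 such genes had a median log2(CPM + 1) of 0.17 and the 2083 others a median of 0 (two-sided permutation p = 0.0001, the smallest that 10000 shuffles can give). Because 1480 of the 2202 genes had no count, these medians lie at or next to the floor, and they were both 0 when either replicate was left out or strand was ignored, so neither the call nor its loss says much. With a copy defined by a shared stretch of at least 20 bases, the direction turned. The 1087 genes with such a stretch had a median of 0 and the 1115 others a median of 0.17 (two-sided permutation p = 0.0001), a difference of -0.17. The difference of the means, a statistic chosen after seeing the data, was 1.28 for the copy number in the symbol and -1.20 for the shared stretch (two-sided permutation p = 0.0001 each), and the former was 1.23 and 1.33 with a replicate left out and 1.07 without strand.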

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

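All tests of explanations in this part were chosen after the results were seen. With 1 group of 2 libraries, there was neither an outlier test nor a contrast between groups.

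Signals were present in read classes that the comparisons did not use, each above the 3 counts that a count of 0 allows. Reads mapped to several places numbered 4968988 in replicate 1 and 4868319 in replicate 2. Uniquely mapped reads in no microRNA gene numbered 545874 in replicate 1 and 452439 in replicate 2. On the 2135 microRNA genes that overlap no other microRNA gene, 117 reads in replicate 1 and 101 in replicate 2 lay on the opposite strand, against 2789929 and 2965269 on the strand of the gene. Of these, 72 and 48 lay on Mir122, which had 518 and 373 reads on its own strand and was singled out after its values were seen.

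The 4 genes Mir1a-1, Mir1a-2, Mir133a-1 and Mir133a-2 had 251 counts or fewer in each library, and a candidate explanation is that reads shared between copies enter no gene. Each of them shares at least 28 bases with another microRNA gene, and 47.2% of the reads mapped to several places. In 15 of 21 other clusters that hold both kinds of gene and a member at 10 CPM or more, the members with a shared stretch of at least 22 bases lay below those without one, with a median difference of -3.69 in log2(CPM + 1) (exact two-sided binomial p = 0.0784). The test misses the threshold, so by it the explanation stays open and cannot be told apart from a low level of these genes. It was run on other clusters, though, and reads within the shared stretches of these 4 genes enter no gene whatever its result. The counts of these 4 genes therefore cannot show that miR-1 and miR-133a are low. No biological explanation was tested, because the places of the reads with several matches were not used here.

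Some neighbouring microRNA genes moved apart between the libraries, and the pairs given here were chosen after their values were seen. Mir15a had a log2 ratio of 1.26 and Mir16-1, which lies 54 bases away, had -1.38. Mir93 had -1.11 and Mir106b had 0.81. Mir16-1 shares at least 22 bases with another microRNA gene, and reads within that stretch enter no gene. Its ratio therefore rests on the remaining reads. The GC content of the whole hairpin is argued against, since 99.8% of the SD of the log2 ratios of 256 genes was left after a linear fit. The GC content of the mature sequences was not tested. A different amount of primary transcript, from transcription or from the cell types sampled, would bring the log2 ratios of neighbours together. Those of 73 neighbouring pairs at 10 CPM or more differed by 0.81, against 0.92 in shuffles (one-sided permutation p = 0.1116), so its part in these ratios cannot be told apart from other causes with 1 pair of libraries. A recovery in library preparation that depends on the mature sequence may contribute: 47 pairs of genes at different places that share at least 15 bases differed by 0.46 in log2 ratio, against 0.92 in shuffles (one-sided permutation p = 0.0001, the smallest that 10000 shuffles can give), and without the let-7 family 30 pairs differed by 0.63 against 0.94 (permutation p = 0.0105). For pairs that share 20 bases or more, reads within the shared stretch enter no gene. Their counts may leave out reads of the mature sequence, so they say little of its recovery. The threshold was not passed over the 11 pairs outside the let-7 family with no shared stretch of 20 bases (permutation p = 0.0565). Joint regulation of related genes, or maturation and decay that differ between neighbours in the 2 animals, stay open and were not tested.

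Mir206 was higher in replicate 2 by 8.11 times (exact 95% interval 6.78 to 9.77, counting error only), and skeletal muscle RNA in that sample is a candidate explanation. Mir133b of the same locus, the other gene of the list fixed for skeletal muscle, changed by 0.863 times (0.447 to 1.66), which lies below the ratio of Mir206. This is 1 marker with 22 counts in replicate 1. Mir133b shares 21 bases with Mir133a-1, and reads within that stretch enter no gene, so a rise could go uncounted. The data also do not show whether its counts come from skeletal muscle or from the heart itself, in which case they would hide a rise. The explanation therefore cannot be told apart from a difference between the animals or the libraries. Other abundant microRNAs of skeletal muscle are also made in heart.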

How the results depend on the processing

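The alternatives with a shared stretch of 22 bases, without genes that share a stretch and with the mean in place of the median of the copies were chosen after seeing the data. No paired analysis was possible because there is 1 group. The count of detected genes ranged from 238 to 398 over its alternatives (337 as reported), the biological coefficient of variation from 0.361 to 0.409, and the genes that differed between the libraries from 176 to 213. These counts stayed within 1.5 times and the coefficient within its bootstrap interval. Of gene levels, list shares and pair ratios other than those given below, 60 moved by more than 1 SD without strand, 28 over all uniquely mapped reads and 12 without Mir378a. The share of reads in microRNA genes was 35.8% on the strand of the gene, 27.6% without strand and 8.19% on the opposite strand. The share of the 10 most abundant genes was 68.5% without strand and 58.6% over all uniquely mapped reads, and the endothelial share was 0.000758% without strand. The log2 ratio of Mir144 to Mir451a was 10.17 without strand. In all, 18 genes with at least 100 counts in replicate 1 kept under 1% of them without strand, and all 18 overlap a microRNA gene on the opposite strand, which shows the cause. Leaving out a replicate turned the ratio of Mir208a to Mir499 (-0.97 to 0.77) and of the Mir1a genes to Mir206 (-2.75 to 0.92). The neighbour difference was -0.38, and at 2 kb it was -0.24 and no longer passed, while its permutation p ranged from 0.0001 to 0.0452 elsewhere. The copy difference was 0.17, and it was 0 without strand and 0 to 0 with a replicate left out. It was -0.17 with a shared stretch of 20 or of 22 bases. These medians lie at or next to the floor, and the difference of the means was 1.28. The replicate ratio of Mirlet7g turned to 0.048 without the low-count filter and 0.0033 without strand, and that of Mir499 to 0.011 without the filter. The counts of both genes were the same in each setting, so these turns come from the scaling alone. The TMM library sizes of replicates 1 and 2 were 3634112 and 3828155 as reported. They were 3732500 and 3727245 without the filter, and 2834263 and 2919152 without strand. Of the 59 named genes whose ratio between replicates passed, 3 no longer did with DESeq2 size factors, 5 without the filter and 0 with plain totals. Without strand, 4 no longer passed (Mirlet7g, Mir126a, Mir499 and Mir200c) and 7 were not tested. Leaving out a replicate gives no value for the spread or the comparison between the replicates. Depth limits what can be said of genes with few counts. For those of Mir133a the counting rule also does, because they share 31 bases and reads within that stretch enter no gene.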

Other observations

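The gene groups in this part were chosen after the data were examined. Most of the large microRNA cluster in an intron of Sfmbt2 on chromosome 2 was silent in these counts. Of its 119 genes, 104 had no count in either library and 7 were detected, and the group summed to 1086 CPM ± 22.9 (SD, n = 2). Mir467d held most of it, at 688 CPM ± 60.8. The cluster is repetitive, and Mir467d shares 60 bases with another microRNA gene, so these levels are uncertain. The Mir302 cluster, known from pluripotent cells, summed to 10.9 CPM ± 4.22 with 2 of 4 genes detected, and the pluripotency-linked cluster from Mir290a to Mir295 summed to 2.81 CPM ± 0.484 with 0 of 7 genes detected. Genes on chromosome X summed to 28884 CPM ± 684, with 32 of 142 detected.

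By position, the 824 genes called intronic held 45.8% ± 2.73 of the counts. The 309 called exonic, which overlap an exon of any annotated transcript of their host, held 27.7% ± 4.43. The 1069 with no host gene on their strand held 26.5% ± 1.70 (SD, n = 2 each). The host gene with the highest share was Ppargc1b, through Mir378a. The detected genes were 149 called intronic, 78 called exonic and 110 with no host.

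Counts of Mir9-3, a gene with copies elsewhere that did not pass the low-count filter, were 101 in replicate 1 and 1 in replicate 2, and those of Mir26a-1 were 261 and 11. No explanation was tested for either.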
